A study of Homo sapiens with 6 samples.

How the data were processed

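Gene expression was measured in A-498 cells, a human renal cell carcinoma line, in 3 untreated cultures and 3 cultures treated with 1000 µM zebularine for 120 h. Per the labels' protocols, medium was changed and cells were split during the treatment, total RNA was extracted with RNAzolB and checked on a Bioanalyzer, and biotin-labelled cRNA was hybridised to Affymetrix arrays. Each culture gave 1 array. Groups and replicate numbers were taken from the sample titles, which call the replicates biological, and per the labels the untreated and treated array of 1 number carry the same experiment name.

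The deposited values are linear probe set intensities, 1 per probe set and array. Per the submitters' processing notes they were made with MAS5, whose version and settings are not given in the sources used here. MAS5 subtracts background and mismatch signal and scales each array, and in the deposited intensities the mean of the values between the 2nd and 98th percentile was close to 500 on each array. Dim MAS5 signals are noisy, and detection calls were not used here. For that reason a floor and a filter were applied: all values were taken as log2(signal + 16.34), where the pseudocount is the median of all values divided by 8, and a probe set was tested if its signal reached 78.6, the 40th percentile of all values, on at least 3 of the 6 arrays. A fold change on this scale understates the change of dim genes. No further normalization between arrays was applied.

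Of 22277 probe sets 62 controls were left out, and 13545 of the other 22215 passed the filter while 8670 were removed. The platform annotation gave 19070 probe sets 1 gene symbol, 1043 several symbols and 2164 no symbol listed; only those with 1 symbol were named. This left 11957 tested probe sets with 1 symbol for 7938 genes, each represented by its probe set with the highest mean signal. Of the 19070 symbols, 19058 were matched by Entrez number to a RefSeq table of the human genome, which changed 0 of them. Chromosomes came from the same table, and no coordinates were used.

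Treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided). Benjamini-Hochberg adjustment ran over all 13545 tested probe sets, for the counts of probe sets and of genes alike, and a call needed an adjusted p under 0.05. Such p-values measure the spread between these cultures of 1 cell line and say nothing about other lines. Gene lists were compared with all other tested genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 20 of 22 lists with at least 5 tested genes, and beside it with a correlation estimated per list and with fry. The lists covered cancer-testis and imprinted genes, genes reported methylated in kidney tumours, interferon response, MHC class I and II, NF-kappaB and p53 targets, mitosis, DNA replication, DNA methylation machinery and pyrimidine nucleoside metabolism. They also covered HIF targets, the ATF4 response, cholesterol synthesis, epithelial, mesenchymal and kidney tubule markers, markers of other cell types, metallothioneins, histones and ribosomal proteins. Control ratios per array were compared with exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

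The test, the lists, the filter, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 10 largest rises and 10 largest falls among called genes whose 3 paired differences have the same sign, up to 4 called members of each list with the smallest p or, with none called, its 2 brightest tested members, and DNMT1, DNMT3A, DNMT3B, UCK2 and CDA. Of the rises, 1 is not reported here. Genes called in opposite directions by different probe sets would have been named too. Genes outside this rule are said to have been chosen after their values were seen.

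Whether the experiment numbers pair the arrays was checked: the deviations of both same-numbered arrays from their group means correlated at 0.323, 0.21 and 0.272 across probe sets in experiments 1, 2 and 3, each the highest for its number. Probe sets are not independent replicates, so these values describe the arrays. Counts with the experiment as a block are therefore given where they change a call over all probe sets. The paired differences of the 3 experiments correlated across 13545 probe sets at 0.253 to 0.397. As a check for repeated arrays, equal values were counted: no 2 arrays shared more than 0.198% of them.

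The fits were tested on simulated arrays of 13545 probe sets with 100 changed 2-fold and 100 changed 4-fold. Without a shared experiment effect the unblocked fit recovered 5% and 50% of these and the blocked fit 0% of both. With such an effect the unblocked fit recovered 2% and 44% and the blocked fit 16% and 59%, and false calls were at most 3. The size of the effect was taken from the spread of the means of same-numbered arrays. That spread also holds part of the noise of the single arrays, so the simulated effect was stronger than the pairing in the data. The gain of the blocked fit in the simulation is therefore overstated. A simulated list of 30 genes shifted by 0.6 was called by limma's camera in 50 of 50 draws and an unshifted one in 1 of 50. Genes were drawn independently there, while the correlation estimated within the tested lists reached 0.717. The 1 in 50 is therefore not the rate of false calls for lists whose genes move together.

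Alternatives covered other pseudocounts, no filter or a stricter one, quantile or median normalization between arrays, no variance trend, a 2-fold minimum, the mean of all probe sets of a gene (adjusted over genes), the block, and leaving out each array or experiment. The block with quantile normalization and the block without each experiment were added after the data were seen.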

Results

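The series asked which genes change expression overall when A-498 cells are treated with zebularine. A-498 is an established human cell line from a renal cell carcinoma, and zebularine is a cytidine analogue used to inhibit DNA methyltransferases. Total RNA was measured on 6 Affymetrix arrays, 3 from untreated cultures and 3 from cultures kept for 120 h with 1000 µM zebularine. Each of 3 experiments gave 1 untreated and 1 treated array. By the series description, the treated cells showed no obvious toxicity in an XTT viability assay, and cultures were split during the treatment.

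Each array held 22277 probe sets, and array medians ran from 118 to 141 signal units. Both arrays of experiment 3 were dimmer at their brightest signals, with maxima of 31176 and 28720.5 against 66290 to 71174 on the other 4. The median of 18 spike-in control probe sets was 1239 on the untreated and 1457 on the treated array, against 3551 to 4103 on the other 4. The 90th percentile of the other probe sets was not lower in experiment 3, at 1599.7 and 1575.9 against 1526.5 to 1551. The ratio of 3' to 5' signal, a sign of RNA integrity and labelling, was 1.26 ± 0.233 for GAPDH in untreated and 1.17 ± 0.165 in treated cultures (SD, n = 3; exact two-sided permutation test, p = 0.6). For ACTB it was 2.40 ± 0.695 and 2.93 ± 2.03 (exact two-sided permutation test, p = 0.9). The GAPDH ratio was lower on the treated array in each of the 3 experiments. With 3 arrays against 3 such a test cannot give a p below 0.1, and the number of arrays limits the precision of every value.

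INHBA was among the genes that rose most after zebularine. INHBA, which encodes the beta A subunit of activin and inhibin, went from a signal of 10.5 ± 5.67 in untreated to 479 ± 170 in treated cultures (SD, n = 3). PLAT, the tissue plasminogen activator, went from 34.7 ± 25.6 to 1028 ± 859, and the secretory granule protein gene SCG5 from 57.6 ± 47.5 to 834 ± 466. On the log2(signal + 16.34) scale these are rises of 4.16 ± 0.47, 4.08 ± 0.61 and 3.56 ± 0.53 (standard error; limma, Benjamini-Hochberg adjusted p = 0.0113, 0.0206 and 0.0206). Collagen XIII (COL13A1) rose by 3.33 ± 0.48 (limma, adjusted p = 0.0206). NT5E, the ecto-5'-nucleotidase CD73 that makes adenosine from AMP, rose by 2.44 ± 0.32 (limma, adjusted p = 0.0171), from 202 ± 98.9 to 1110 ± 172. The calcium-activated potassium channel gene KCNN4 rose by 2.48 ± 0.44, the diacylglycerol kinase gene DGKI by 2.38 ± 0.45, and the metallothionein genes MT2A and MT1H by 2.28 ± 0.34 and 2.28 ± 0.39. Each of these 9 genes was higher on the treated array in all 3 experiments, which the naming rule required.

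CDH6 was among the genes that fell most. CDH6, a cadherin of kidney epithelium, fell by 2.85 ± 0.42 (limma, adjusted p = 0.0206), from 1400 ± 812 to 162 ± 54.2 signal units (SD, n = 3). CDH17, another cadherin gene, fell by 2.55 ± 0.51 (limma, adjusted p = 0.0476). FN1, fibronectin, fell by 1.82 ± 0.29 (limma, adjusted p = 0.0241), from 6361 ± 199 to 1892 ± 748. Further falls were seen for TMT1A (fell by 2.81 ± 0.53), the muscle filament gene NEB (fell by 2.37 ± 0.46) and the secreted Wnt modulator gene SFRP4 (fell by 1.91 ± 0.31). HLA-DRB1 fell by 1.75 ± 0.30, at a probe set that can also bind transcripts of related genes. The nucleoside transporter gene SLC29A3 fell by 1.82 ± 0.36, the sulfotransferase gene CHST2 fell by 1.73 ± 0.29 and the adenosine A1 receptor gene ADORA1 fell by 1.68 ± 0.33. All 10 were lower on the treated array in all 3 experiments, which the naming rule required.

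**Figure D1:**
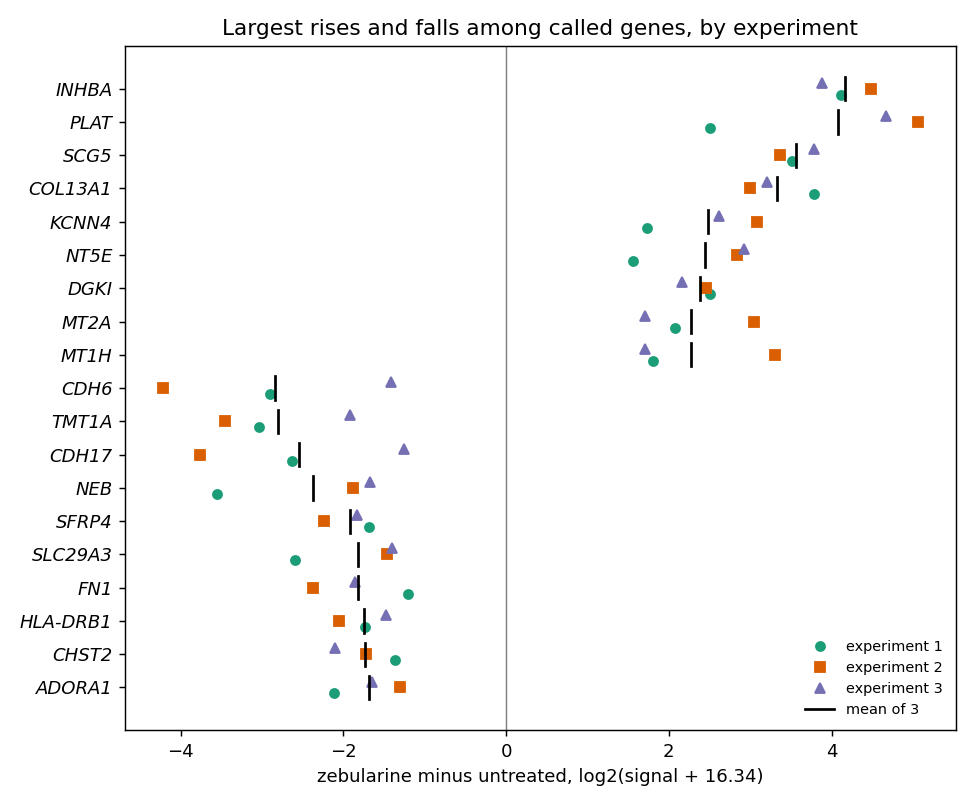
Treated minus untreated difference on the log2(signal + 16.34) scale (horizontal axis) for 9 of the 10 largest rises and the 10 largest falls among called genes, 1 symbol per experiment and a black bar for the mean of the 3. Every symbol of a gene lies on the same side of 0, as the naming rule required. PLAT spreads from 2.51 to 5.06 and CDH6 from -4.22 to -1.41.

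In all, limma with Benjamini-Hochberg adjustment over all tested probe sets called 51 of 7938 tested genes at an adjusted p under 0.05, 28 higher and 23 lower after zebularine, and each changed at least 2-fold. It called 84 of 13545 tested probe sets, 44 higher and 40 lower. At an unadjusted p under 0.05 there were 1039 genes and 1702 probe sets. The experiment numbers paired the arrays, and with the experiment as a block the same test called 353 genes (172 higher, 181 lower) and 572 probe sets (258 higher, 314 lower), including all 51 genes and all 84 probe sets called without the block. The unblocked count rested on single arrays: it was 0 in limma without zebularine 2 (792 genes at an unadjusted p under 0.05), 11 without zebularine 3, 12 without untreated 3, 13 without untreated 1, 48 without zebularine 1 and 64 without untreated 2. It was 31 with a smaller pseudocount or none, 25 without the filter on dim probe sets and 5 without limma's mean-variance trend, while the blocked count was 118, 644 and 210 without experiment 1, 2 and 3. In a count chosen after the data were seen, 1 array at a time was left out. This moved the value of 0 of 22 called genes picked by the naming rule by over 1.5 times. Among such genes that were not called it moved 32 of 33. The contrast follows from the selection, since called genes have large changes for their spread and many of the others lie near 0. It therefore does not measure stability. Among alternatives that used all arrays, INHBA was called in 11 of 11, CDH6, FN1, NT5E, PLAT and SCG5 in 10 of 11, and ADORA1 and CDH17 in 5 of 11.

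Of the 51 called genes, 15 had 23 further tested probe sets, of which 21 changed in the same direction and 8 were called. The exceptions were a probe set of COL13A1 at -0.49 (limma, adjusted p = 0.82) and a probe set of TMT1A at 0.03 (limma, adjusted p = 0.985). No gene was called in opposite directions by 2 probe sets. INHBA, PLAT, SCG5, COL13A1, KCNN4 and DGKI had untreated means below 78.6, the level used to filter dim probe sets, so the size of their rise depends on the pseudocount: over the pseudocounts tried, the rise of INHBA ran from 2.79 to 5.63 and that of COL13A1 from 2.27 to 4.34. Averaging the probe sets of COL13A1 gave 1.47 (limma, adjusted p = 0.215).

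Transcripts of the drug's own targets did not pass the test. DNMT1, the maintenance DNA methyltransferase, stood at 1003 ± 135 in untreated and 1226 ± 241 in treated cultures, a log2 difference of 0.27 ± 0.25 (limma, adjusted p = 0.704). DNMT3B, a de novo methyltransferase, stood at 948 ± 430 and 558 ± 240, a difference of -0.73 ± 0.36 (limma, adjusted p = 0.423, and 0.0875 with the block), lower in all 3 experiments and at -0.39 without untreated 1. DNMT3A was left out of the test as too dim, with signals from 27.4 to 159. CDA, the cytidine deaminase, which zebularine also inhibits, differed by 1.41 ± 0.64 (limma, adjusted p = 0.392), with pair differences of 3.03, 1.29 and -0.09. UCK2, a uridine-cytidine kinase, was not analysed here. Over the 24 tested genes of the DNA methylation and silencing machinery none was called, over all probe sets or adjusted over the list alone; the median log2 difference was 0.06 and the mean -0.05, and the direction of limma's camera was down (adjusted p = 0.854). With the block, adjusted over the list alone, EED was higher and CBX5, TRIM28 and DNMT3B lower, named after their values were seen. Its brightest members CBX3 and CBX1 differed by 0.13 and 0.06.

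Metallothionein genes, whose products bind zinc and copper, were higher together. All 6 tested members were higher in treated cultures, with a median log2 difference of 1.81. MT1X (412 ± 162 to 1968 ± 380), MT2A (1106 ± 554 to 4973 ± 482) and MT1H (182 ± 98.3 to 841 ± 9.01) rose (limma, adjusted p = 0.0171, 0.0206 and 0.0295), and all 6 passed when adjusted over the list alone. With the experiment as a block all 6 were called over all probe sets, MT1E, MT1F and MT1G included at differences of 1.22, 1.10 and 1.37. The camera test with its preset correlation gave an adjusted p of 1.48e-10 for the list, adjusted p = 0.352 with an estimated correlation, and fry, which tests whether a list's genes move one way on balance, gave 0.0484 (0.159 with the block). The probe sets of these genes are of a type that can bind transcripts of related genes, so the single members are uncertain. Probe sets of another type, for MT1G, MT1M, MT3 and MT4, were too dim to test. That of MT1G went from 76.7 to 30.5, 60.1 to 17.1 and 5.1 to 10.1 in experiments 1, 2 and 3.

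Interferon response genes lay higher in treated cultures, by amounts that differed between the experiments. Of 39 tested genes 87.2% had a positive mean log2 difference, with a median of 0.72, and the list's median was 0.26 in experiment 1, 0.22 in experiment 2 and 1.94 in experiment 3. SAMD9, an interferon-induced antiviral gene, rose by 2.06 ± 0.41 (limma, adjusted p = 0.0475) and was the 1 member called over all probe sets, while 9 passed adjusted over the list alone. With the experiment as a block 10 members rose and 1 fell over all probe sets. Chosen after their values were seen, ISG15, OAS2 and IFIT1, all induced by interferon, differed by 1.74 ± 0.58, 2.01 ± 0.57 and 2.02 ± 0.75 (limma, adjusted p = 0.237, 0.167 and 0.285, and 0.018, 0.0366 and 0.0315 with the block). The member that fell was LGALS3BP, at -0.69 (adjusted p = 0.0372 with the block). The camera test gave the list an adjusted p of 1.69e-08 with its preset correlation, adjusted p = 0.819 with an estimated correlation, and fry 0.793. The median was 0.50 without untreated 3, 0.36 without zebularine 3 (limma's camera, adjusted p = 0.0476) and 0.22 without both arrays of experiment 3 (limma's camera, adjusted p = 0.0516).

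**Figure D2:**
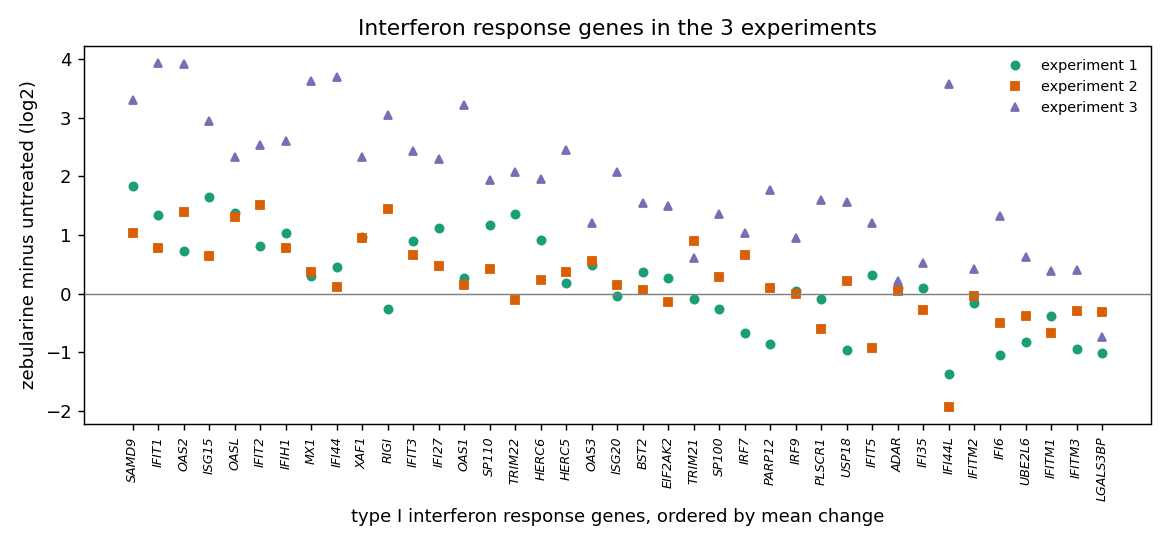
Treated minus untreated difference on the log2(signal + 16.34) scale (vertical axis) for each of the 39 tested interferon response genes (horizontal axis, ordered by mean change), 1 symbol per experiment. In 37 of the 39 genes the symbol of experiment 3 is the highest of the 3.

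Genes of mitosis lay higher after treatment without passing 1 by 1. Of 46 tested genes 93.5% had a positive mean difference, with a median of 0.55 on the log2 scale; 0 were called by limma over all probe sets, 15 were higher adjusted over the list alone, and 11 rose over all probe sets with the experiment as a block. PTTG1, the separase inhibitor securin, differed by 0.92 ± 0.32 (limma, adjusted p = 0.26, and 0.0142 with the block), and CKS2, a subunit of cyclin-dependent kinases, by 0.40 ± 0.29 (limma, adjusted p = 0.606). Chosen after their values were seen, the proliferation marker MKI67 stood at 1099 ± 141 in untreated and 2441 ± 518 in treated cultures (limma, adjusted p = 0.0756, and 0.00948 with the block), and the mitotic kinase gene CDK1 at 1695 ± 341 and 4211 ± 1510 (limma, adjusted p = 0.0862, and 0.0118 with the block). The list's median was 0.223, 0.911 and 0.695 in experiments 1, 2 and 3. The camera test gave an adjusted p of 1.1e-13 for the list, adjusted p = 0.562 with an estimated correlation, and fry 0.248.

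DNA replication genes had a smaller median difference of 0.20 over 43 tested genes, none called in limma over all probe sets or adjusted over the list alone. The thymidylate synthase gene TYMS differed by 0.24 ± 0.26 and the replication protein gene RPA3 by 0.26 ± 0.27. TYMS was at 0.05 without zebularine 2 and RPA3 at 0.07 without untreated 1. With the block ORC6 and PCNA were called (limma, adjusted p = 0.045 and 0.0416), at 0.90 and 0.93. The camera test's adjusted p of 0.0283 became adjusted p = 0.983 with an estimated correlation. The call also ended without untreated 1 (median 0.07, p 0.616), zebularine 2 (0.254), untreated 3 (0.0642), zebularine 3 (0.238), experiment 1 (0.0537) or experiment 3 (median 0.09, p 0.309). Without untreated 2 or zebularine 1 the median was 0.37 and 0.36 (limma's camera, adjusted p = 0.000185 and 0.000336).

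Targets of p53 had a median difference of 0.23 over 25 tested genes, none called over all probe sets and 2 higher adjusted over the list alone. These were TP53I3 and the death receptor gene FAS, at 1.21 ± 0.26 and 1.07 ± 0.25 (limma, adjusted p = 0.0644 and 0.0804, and 0.0121 for both with the block), which were named after their values were seen. The brightest members, RPS27L and the growth factor gene TGFA, differed by 0.26 ± 0.24 and 0.84 ± 0.40, the latter 0.29 without untreated 2 and 1.22 without untreated 1. The camera test's adjusted p of 0.0279 became adjusted p = 0.562 with an estimated correlation. It was 0.0736 without zebularine 1, 0.0751 without zebularine 2, 0.199 without experiment 2 and 0.12 without untreated 2, where the median was 0.03, and between 0.00477 and 0.0434 without each of the other arrays.

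Kidney tubule markers had a median difference of -0.49 over 9 tested genes, of which CDH6 fell, over all probe sets and adjusted over the list alone, and 8 were not called. The camera test gave an adjusted p of 0.0283, adjusted p = 0.562 with an estimated correlation, 0.0925 with the block, where the median is the same, and 0.367 without the filter, where the median was -0.09. It was 0.164 without untreated 1 (median -0.34), 0.0532 without zebularine 1, 0.0793 without untreated 2 and 0.0713 without zebularine 2. The list's median was -0.943, -0.492 and -0.0891 in experiments 1, 2 and 3, and -0.295 without experiment 1.

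Genes of the ATF4 and unfolded protein responses had a median difference of -0.31 over 34 tested genes, none called in any fit, with medians of -0.65, 0.54 and -0.85 in experiments 1, 2 and 3. The chaperone gene HSPA5 differed by 0.12 ± 0.28 and ATF4 itself by 0.18 ± 0.32. The camera test's adjusted p of 0.0279 became adjusted p = 0.983 with an estimated correlation, 0.635 without untreated 1 (median -0.07), 0.328 without untreated 3 (-0.16) and 0.238 without zebularine 3 (-0.19). Without untreated 2 the median was -0.83 (limma's camera, adjusted p = 3.15e-11).

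Cytosolic ribosomal protein genes had a median difference of -0.17 over 54 tested genes, none called over all probe sets or adjusted over the list alone, and 2 were called lower with the block. Those were RPL3 at -0.59 and RPL10A at -0.61 (limma, adjusted p = 0.0312 and 0.0415 with the block). RPS4X differed by -0.22 ± 0.31, and RPL37A by -0.11 ± 0.30, which became 0.09 after quantile normalization. The camera test's adjusted p of 0.0279 became adjusted p = 0.983 with an estimated correlation and 0.568 after quantile normalization, where the median was -0.04. It was 0.0605 without untreated 1, 0.111 without zebularine 1, 0.899 without untreated 2 (median -0.04) and 0.916 without zebularine 3 (-0.02). The median was -0.34 without untreated 3 and -0.35 without zebularine 2 (limma's camera, adjusted p = 8.7e-06 and 4.29e-07).

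Of 20 lists with at least 5 tested genes, camera with its preset correlation called these 8, 5 up and 3 down, and 7 with the block. With an estimated correlation it called 0 in either fit (1 list at an unadjusted p under 0.05 without the block). The directional test of fry called 1, the metallothioneins, without the block and 0 with it. The other lists did not pass camera. A mixed test of fry counts changes in either direction and does not compare a list with other genes. It called 9 lists without the block and 11 with it.

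**Figure D3:**
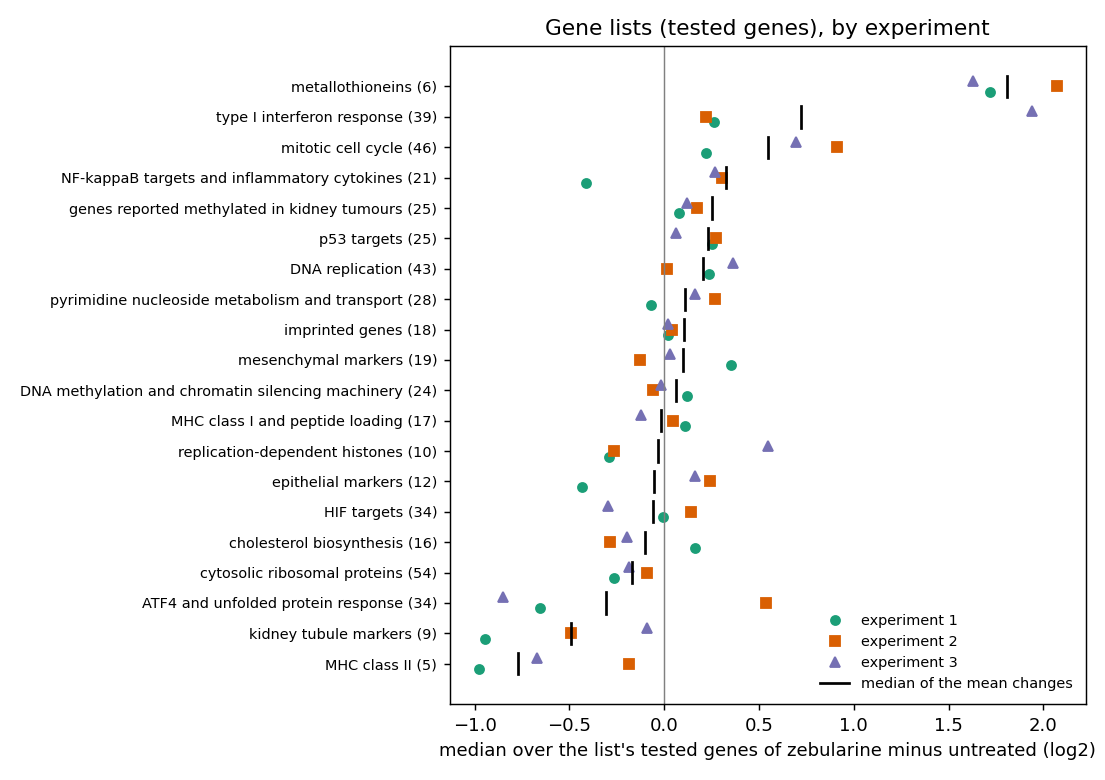
Median over each list's tested genes of the treated minus untreated difference on the log2 scale (horizontal axis), 1 symbol per experiment, with the number of tested genes in parentheses and a black bar at the median of the genes' mean differences. Metallothioneins lie at 1.72, 2.07 and 1.63 in experiments 1, 2 and 3, while interferon response genes reach 1.94 in experiment 3 and 0.26 and 0.22 in the others.

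Neither list of antigen presentation genes passed the camera test with all arrays. Of 12 genes of MHC class II on the array, whose products show peptides to helper T cells, 5 were bright enough to test. Of these HLA-DRB1 fell and 2 were lower adjusted over the list alone. The median difference was -0.77, and -0.13 without the filter (limma's camera, adjusted p = 0.0975, and 0.0328 without zebularine 2). The further one lower adjusted over the list alone was HLA-DMA at -0.77 ± 0.29. The HLA-DRB1 value comes from a probe set of a type that can bind transcripts of related genes. Which transcript fell is therefore uncertain. Over 17 genes of MHC class I and peptide loading none was called; the median was -0.02, the mean -0.01 and the direction of limma's camera up (adjusted p = 0.949). Its brightest members B2M and HLA-C differed by 0.17 ± 0.28 and -0.20 ± 0.26.

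Among inflammatory genes and other targets of NF-kappaB, 21 were tested with a median difference of 0.33; none was called over all probe sets, and 3 were higher adjusted over the list alone (limma's camera, adjusted p = 0.577). With the block the cytokine genes CXCL8, IL1B and IL6 rose, at 2.86 ± 0.60, 1.68 ± 0.44 and 1.75 ± 0.54 (limma, adjusted p = 0.0154, 0.0327 and 0.0211 with the block, against 0.0532, 0.118 and 0.205 without it), and were named after their values were seen. In the same fit the adhesion molecule gene VCAM1 fell by 1.04 and TNFAIP6 fell by 1.25 (limma, adjusted p = 0.0275 and 0.0345 with the block), the latter at -0.68 without untreated 1. TNFAIP2 differed by -0.53 ± 0.31. The list's median was -0.03 without untreated 2 and 0.47 without experiment 1, where the list passed (limma's camera, adjusted p = 0.0267, and 0.0222 with the block).

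Among classes that DNA methylation can silence, the 2 lists with enough tested genes did not pass the camera test. Of 57 genes reported methylated in kidney tumours on the array 25 were bright enough to test, and of 30 imprinted genes 18. The rest were removed by the filter as too dim, so these tests say nothing about re-expression among them. Genes reported methylated in kidney tumours had 25 tested members with a median difference of 0.25 (limma's camera, adjusted p = 0.267), which was 0.12 without untreated 2 and 0.13 without experiment 1: SFRP4 fell, 24 were not called, and adjusted over the list alone SFRP4 was lower and XAF1 higher. With the block XAF1 and MT1G rose, at 1.41 and 1.37, and adjusted over the list alone 5 members were higher and 2 lower. XAF1 is also in the list of interferon response genes and MT1G in that of metallothioneins, and both of those lists lay higher after treatment. The MT1G value comes from a probe set that can bind transcripts of related genes. Another MT1G probe set, too dim to test, went from 76.7 to 30.5, 60.1 to 17.1 and 5.1 to 10.1 in experiments 1, 2 and 3. Of 41 cancer-testis genes on the array 3 were bright enough to test and none was called; PRAME, expressed in many tumours, stood at 856 ± 167 and 1088 ± 174 (limma, adjusted p = 0.618), and SPA17 differed by -0.04 ± 0.37. Over 18 imprinted genes none was called (median 0.10; limma's camera, adjusted p = 0.926; 1 lower with the block). GNAS differed by -0.03 ± 0.28, which became 0.05 after quantile normalization, and TFPI2 by -0.45 ± 0.29.

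Metabolic and structural lists were mixed. In pyrimidine nucleoside metabolism NT5E rose and the other 27 genes were not called (median 0.11; limma's camera, adjusted p = 0.227). That list passed without zebularine 1 (median 0.28; limma's camera, adjusted p = 0.0163) and with the block without experiment 1 (median 0.20; limma's camera, adjusted p = 0.0475), and its median was -0.03 without zebularine 3. Targets of HIF, the hypoxia factor, had a median of -0.06 over 34 genes (limma's camera, adjusted p = 0.854), 1 higher adjusted over the list alone, P4HA2 at 1.36; the glycolytic gene LDHA differed by 0.02 ± 0.27 and NDRG1 by -0.48 ± 0.35 (limma, adjusted p = 0.048 with the block, in which 1 member rose and 3 fell, and 0.122 with the block after quantile normalization), with -0.19 without untreated 1 and -0.86 without zebularine 1. Cholesterol synthesis genes (16 tested) had a median of -0.10, with FDPS at -0.03 and MSMO1 at -0.12 (limma's camera, adjusted p = 0.577). Epithelial markers (12 tested) had a median of -0.06 and a mean of 0.10, with the direction of limma's camera up (adjusted p = 0.949), and the keratin genes KRT18 and KRT8 differed by -0.34 ± 0.25 and -0.38 ± 0.27. Mesenchymal markers (19 tested) had a median of 0.10 (limma's camera, adjusted p = 0.854): FN1 fell, and adjusted over the list alone FN1 was lower and ZEB1 higher. With the block 1 member rose and 2 fell. Replication-dependent histone genes (10 tested) had a median of -0.03 (limma's camera, adjusted p = 0.971), with H2BC12 at 0.04 and H2AC6 at -0.15. Of 23 marker genes of leukocytes, endothelium and erythroid cells on the array, 3 were bright enough to test and none was called; FCER1G stood at 90.7 ± 36.5 and 151 ± 76.9, and ITGAM at 73.5 ± 56.1 and 125 ± 12.8.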

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

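The tests with the experiment as a block after quantile normalization, and with the block while leaving out each experiment, were chosen only after the data were seen; the other alternatives were planned. In limma, the count of 51 genes and 84 probe sets became 353 and 572 with the experiment as a block, 31 and 55 with a pseudocount of 1/32 of the median, 31 and 53 with none, 42 probe sets and 25 genes without the filter, and 5 genes and 6 probe sets without the mean-variance trend. The block with quantile normalization gave 367 genes. Leaving out arrays or experiments gave 0 to 64 genes and 0 to 96 probe sets without the block, and 118 to 644 genes and 194 to 1023 probe sets with it; both were 0 in limma without zebularine 2 (792 genes and 1315 probe sets at an unadjusted p under 0.05) and without experiment 2 unblocked (968 and 1583). The cause was not tested.

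Of 20 lists, limma's camera called 8. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05), and the directional test of fry called 1. Leaving out arrays or experiments gave 4 to 8. With camera's preset correlation, metallothioneins and mitosis kept their call in 23 of 23 alternatives, arrays left out included. Interferon response kept it in 22, p53 targets in 18, DNA replication, the ATF4 response and ribosomal proteins in 16, and kidney tubule markers in 11 of 22. The estimated correlation and fry are not among these alternatives. Mitosis lost its call with both (camera, adjusted p = 0.562, and fry, adjusted p = 0.248). Metallothioneins lost it with the estimated correlation (camera, adjusted p = 0.352).

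Among genes picked by the naming rule, none of those called changed sign; genes named after their values were seen were followed only with the block. Values near 0 did. The median of epithelial markers became 0.0347 without a pseudocount and 0.0525 with the filter at the 60th percentile, which also gave -0.264 for mesenchymal markers and 0.0448 for histones. Quantile normalization gave 0.048 for GNAS and 0.0905 for RPL37A, with or without the block, and the mean of all probe sets of a gene gave 0.147 and 0.171.

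Leaving out arrays or experiments moved these list medians across 0: cholesterol synthesis (-0.259 to 0.0769), DNA methylation machinery (-0.0449 to 0.0936), epithelial markers (-0.317 to 0.258), HIF targets (-0.278 to 0.0573), imprinted genes (-0.0584 to 0.184), mesenchymal markers (-0.189 to 0.184), MHC class I (-0.0499 to 0.0603), NF-kappaB targets (-0.0309 to 0.468), pyrimidine metabolism (-0.0296 to 0.275) and histones (-0.308 to 0.189). Single genes that did so were ATF4 (-0.222 to 0.51), CBX1 (-0.0608 to 0.204), FDPS (-0.115 to 0.0485), GNAS (-0.243 to 0.174), H2AC6 (-0.5 to 0.244), H2BC12 (-0.459 to 0.371), HSPA5 (-0.122 to 0.349), LDHA (-0.137 to 0.23), MSMO1 (-0.507 to 0.215), RPL37A (-0.345 to 0.138), RPS4X (-0.494 to 0.0443) and SPA17 (-0.36 to 0.248).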

Other observations

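The tests on interferon genes, on metallothioneins, on cancer-testis probe sets and on list medians in other splits were chosen only after the results were seen. So were the genes named in the next paragraph.

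Further genes and probe sets were called beyond those with the largest changes. The hyaluronan receptor gene CD44 differed by 0.72 ± 0.27 at its brightest probe set (limma, adjusted p = 0.3, and 0.0193 with the block), while 5 of its other probe sets rose by 1.29 to 2.11 (limma, adjusted p = 0.0127 to 0.0464). The integrin gene ITGA2 rose by 2.02 ± 0.38, the drug transporter gene ABCG2 by 1.79 ± 0.36 and the ephrin gene EFNB2 by 1.63 ± 0.26 (limma, adjusted p = 0.0397, 0.0483 and 0.0241). The matrix protease gene MMP7 fell by 1.62 ± 0.30, the transcription factor gene MITF by 1.60 ± 0.31 and the retinal dehydrogenase gene ALDH1A1 by 1.48 ± 0.29 (limma, adjusted p = 0.0337, 0.0458 and 0.0458), each in 3 of 3 experiments. None of these 7 genes is in the gene lists.

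Interferon response genes differed more between treated and untreated in experiment 3 than in the others, in 37 of 39 genes against 32.3% of all tested genes, with a median excess of 1.45. The untreated array of experiment 3 lay at -0.102 from the other untreated arrays, which argues against a low untreated array as the source. Over all tested genes the median difference in experiment 3 was -0.00399, against 1.94 for the list. All arrays had been scaled to a common level, so a value near 0 was largely fixed in advance. It shows only that no uniform shift as large as that of the list remained between the arrays of experiment 3. The median of 18 leukocyte probe sets on zebularine 3 lay at -0.366 from the highest other array, but near the floor (signal 29.2). Single probe sets went either way: FCER1G was highest there (211), while CSF1R read 8.3 there and up to 185.3 on other arrays. At this level the test decides nothing, so admixed leukocytes stay open. A stronger response to the drug in that culture and a stimulus that reached that culture alone may also apply, and the design separates neither.

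Metallothioneins were higher together, and transcripts of 1 gene could light up several of their probe sets. The differences of MT1E and MT1F lay 1.06 ± 0.35 and 1.18 ± 0.27 below that of MT2A in 3 of 3 experiments, so 2 of the 5 other members moved apart from it. Weaker binding of the same transcript would also give a smaller rise, and probe sequences were not checked, so 1 metallothionein transcript lighting up all probe sets stays open. MT1H and MT1X lay at 0.00 and -0.02 from MT2A. Metal in the medium was not measured.

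The paired fit called 6.92 times as many genes as the unpaired one. After quantile normalization, which evens out the dimmer brightest signals of experiment 3, the ratio was 9.66, which argues against that dimness as the cause. Deviations of same-numbered arrays correlated at 0.21 or more, as differences between the experiments that both arrays of a pair share would give, so that explanation may account for the gain.

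Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 51 genes and 84 probe sets and the highest other 0 of each in limma, so 1 of 10 splits was as large for both. At an unadjusted p under 0.05 the real split gave 1039 genes and the highest other 890, untreated 1, zebularine 1 and untreated 3 against the rest, while the 3 others that part all 3 pairs gave 67, 220 and 80. It gave 8 lists and the highest other 9, so 4 of 10 were as large; the 9 came from untreated 1, zebularine 1 and untreated 2 against the rest, and those 3 gave 8, 5 and 5. With the block there are 4 splits, also too few: the real one gave 353 genes in limma and the highest other 0 (1691 and 282 at an unadjusted p under 0.05), so 1 of 4 was as large. In size of median, the real split gave 1.81 for metallothioneins (highest other 1.17), 0.55 for mitosis (0.46), 0.77 for MHC class II (0.57) and 0.25 for genes reported methylated in kidney tumours (0.24), the last 2 not called, but 0.72 for interferon response (highest other 0.76), 0.20 for DNA replication (0.50), 0.31 for the ATF4 response (0.84), 0.23 for p53 targets (0.30), 0.49 for kidney tubule markers (0.67) and 0.17 for ribosomal proteins (0.48). For these last 6 lists another split gave a median as large as the real one.

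Re-expression of silent genes, which loss of DNA methylation could bring, was tested on probe sets that were below 78.6 on all arrays of 1 group and at least at 157.2 on all of the other. 6 went from dim to bright and 7 from bright to dim (exact binomial test, two-sided, p = 1), and other splits gave at most 3 in all; no difference between the directions was found. Dim to bright went PLAT, DGKI, INHBA, COL13A1, MARCHF3 and 1 unnamed probe set; bright to dim went NEB, ACSM3, TMT1A, TBC1D22A, CDH6, RAB26 and PREX2. Of 46 cancer-testis probe sets too dim to test, 5 (10.9%; MAGEB3, CTAG2, SYCP1, DDX43 and TAF7L) had all treated above all untreated arrays and 1 the reverse, where chance gives 5% each way; no signal exceeded 165, and at this level the question stays open.

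Gain or loss of a chromosome in the treated cultures cannot be told apart from no change: the chromosome median furthest from 0 was -0.14, for chromosome 19 (limma's camera, adjusted p = 0.236), between the bounds set for an answer, and 0 of 23 chromosomes passed in limma's camera (1 at an unadjusted p under 0.05). Families of genes that share a symbol stem were tested for groups beyond the fixed lists. Of 230 families outside the called lists, limma's camera called 0 (19 at an unadjusted p under 0.05), the nearest being the SMC genes of chromosome structure (6 genes, median 0.66, adjusted p = 0.0706).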
